A study of Rattus norvegicus with 15 samples.

How the data were processed

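MicroRNA levels were measured with the nCounter assay, in which each miRNA is joined to a sequence tag and single tagged molecules are counted by a coloured barcode. The material was total RNA from adult Sprague Dawley rat cardiomyocytes, extracted with TRIzol after the cells had been plated for 1 h on laminin and unattached cells discarded. There were 15 samples in 5 groups of 3, with 1 lane per sample. The groups were cardiomyocytes given saline vehicle or doxorubicin (DOX) in culture, each for 6 h, and cells from hearts. The hearts were age-matched controls, hearts of animals that received repeated DOX injections, and hearts 4 weeks after myocardial infarction (MI) by coronary ligation. The labels do not say whether the samples of a group came from separate animals or cultures, so the p-values measure only the spread between these samples. The chi-square per degree of freedom over probes was 1.60 to 1.74 between vehicle samples and 1.56 to 1.89 between age-matched controls. It was 1.85 between samples 1 and 2 given DOX in culture, and 2.07 to 42.2 between the other pairs within a group. The low values are little above counting error, so n = 3 cannot be read as 3 animals or cultures. The panel held 420 rat miRNA probes, 6 positive controls, 8 negative controls, 4 housekeeping mRNA probes and 5 non-mammalian spike-in probes.

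The authors deposited a worksheet of 4 sheets. The first deposited sheet holds whole barcode counts per probe without normalization, treated under the unit of expected (estimated) counts. The second holds the same expected counts after the authors subtracted a share of the lane's brightest positive control from 3 probes with a marked background, and set results under 1 to 1. The other two hold signal that the authors scaled by the positive-control sum and then by the sum of miRNA counts. The authors' tables for 3 group comparisons give the signal as group means after quantile normalization, with the p-value and the score (a t statistic) of their test. Among means under 1000, 99.7% are whole multiples of 1/72 within 0.05 of a step, the step that means of 3 lanes have when 24 lanes are quantile-normalized together. A further table whose groups match no sample was not used here. The software behind the authors' tables is not given in the sources used here.

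All models were fitted to the uncorrected counts. A lane's background was the mean plus 2 SD of its 8 negative controls. A miRNA was tested when it lay above background in at least 3 of the 15 lanes, which kept 109 miRNAs, 58 of them above background in every lane. Counts were scaled by TMM and fitted with the robust quasi-likelihood model of edgeR 4.0.16 under R 4.3.3, with all 15 samples and 1 mean per group. Normalized CPM are TMM-scaled and relative to the lane's rat miRNA counts. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a miRNA was called at an adjusted p under 0.05. The SE of a log2 fold change comes from the same model. The 6 comparisons were in vitro DOX with vehicle, in vivo DOX with age-matched controls, MI with age-matched controls, in vivo DOX with MI, vehicle with age-matched controls, and the DOX effect in vivo minus that in vitro.

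Before the data were examined, 18 lists of miRNAs were fixed: heart and striated muscle miRNAs (myomiRs), the miR-30 family, p53-responsive miRNAs, the hypoxia miRNA miR-210, miRNAs reported raised in rodent heart failure or hypertrophy, the miR-29, let-7 and miR-15 families, the miR-17-92 clusters, the miR-23/24/27 cluster, the miR-200 family, the Dlk1-Dio3 cluster, lists for endothelial cells, smooth muscle, fibroblasts, leukocytes and erythroid cells, and a list for brain, liver and islet. The study had chosen the miR-30 family on these samples. The 9 lists with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. List p-values were adjusted over the 54 tests of 9 lists in 6 comparisons.

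The miRNAs named below follow a rule set at the same time. It takes up to 10 miRNAs in each direction with the largest fold change among called miRNAs whose 2 groups do not overlap, and the 5 smallest p-values where fewer than 5 pass. It also takes every measured member of the myomiR, miR-30, p53 and hypoxia lists, and up to 4 called members of each other list. Endothelial, smooth muscle and leukocyte miRNAs outside the rule are given as values, and this choice was made after the values were seen.

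The procedure was tested on simulated data drawn from the mean level and the dispersion of each probe (the median for untested probes). There were 20 simulations for each of 2 settings. Dispersion was the same in all groups, although the real samples of some groups spread more than those of others. The shares below may therefore not hold for the real groups. With 200 of 420 probes changed, the share of 2-fold changes recovered was 69.5% for in vitro DOX, 61.3% for in vivo DOX, 50.6% for MI, 64.0% for in vivo DOX with MI and 54.2% for vehicle with age-matched controls. The share of 4-fold changes recovered ranged from 96.9% to 99.0%. The share of calls that were false was 3.35%, 4.55%, 11.8%, 3.53% and 9.45% in the same order, so MI and the vehicle comparison exceeded the nominal 0.05. With 40 probes changed the false share ranged from 4.19% to 7%. The share of 2-fold changes recovered was then lower, at 52.8%, 47.6%, 41.7%, 39.5% and 51.8% in the same order. Unchanged lists were called in 4 of 1194 tests. These simulations drew each probe independently, so that rate does not hold for lists whose members move together. Under in vitro DOX the estimated correlation was 0.93 for the miR-29 family and 0.29 for the let-7 family.

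The alternatives covered 5 other scalings, DESeq2 1.42.0 with its own test, limma on the authors' sum-normalized values, the authors' corrected counts, subtraction of the lane background, no filter, a filter on all 15 lanes, a fit of the compared groups alone, a fit without robust estimation, a term for replicate number, and omission of each sample in turn. Quantile normalization of the 15 lanes, a stricter filter, omission of 3 samples together and separate controls for the in vivo DOX and MI effects and for the MI and vehicle effects were added after the data had been seen.

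Total miRNA counts ranged from 36977 to 137746 per lane, and the number of miRNAs above background from 73 to 109. The positive-control sum ranged from 4229 to 24224 and was lowest in the MI lanes. The 3 in vitro DOX lanes were on 1 of the 2 cartridges and the other 12 lanes on the other.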

Results

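The study profiled miRNAs in cardiomyocytes damaged by DOX or by MI. DOX is an anthracycline used against cancer that is toxic to heart muscle. Total miRNA counts were 122854 to 137746 per lane for vehicle, 71522 to 104987 for in vitro DOX, 36977 to 62663 for age-matched controls, 54608 to 133965 for in vivo DOX and 40381 to 77375 for MI. The muscle miRNA miR-1 took 17.1% to 26.7% of the counts of a lane, and the 5 most abundant miRNAs together took 44.6% to 52.4%. Of the 109 miRNAs tested, 58 lay above the lane background in all 15 lanes. Counts of the negative controls, relative to miRNA counts, were 118 ± 5.49 CPM in vehicle, 174 ± 39.3 in in vitro DOX, 208 ± 21.7 in age-matched controls, 169 ± 62.6 in in vivo DOX and 105 ± 8.59 in MI (SD, n = 3 each).

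**Figure D1:**
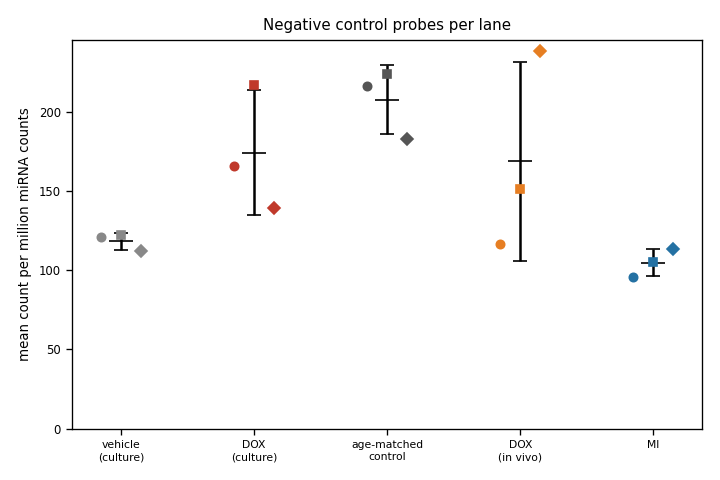
Mean count of the 8 negative controls in CPM of miRNA counts, per sample, in the 5 groups, with the group mean and an error bar of 1 SD (n = 3). The MI samples average 105 CPM and the age-matched controls 208 CPM.

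The first comparison asked how miRNAs change in isolated cardiomyocytes during 6 h with DOX, against saline vehicle. All 3 measured members of the miR-29 family, known repressors of collagen mRNAs, fell. The level of miR-29b fell 7.06-fold (log2 -2.82, SE 0.76, n = 3 per group), from 14191 ± 240 to 1999 ± 2323 CPM (SD), miR-29c fell 4.26-fold and miR-29a 2.71-fold. In vitro DOX replicate 3 held 4682 CPM of miR-29b against 640 and 675 in the other DOX samples, and without it miR-29b fell 21.5-fold and miR-29c 8.13-fold. Of the 8 let-7 members, which are abundant in differentiated cells and so alike in sequence that their probes may share signal, 5 rose, among them let-7c from 14955 ± 1268 to 36069 ± 15018 CPM (2.41-fold, log2 1.27, SE 0.30), let-7f 2.25-fold, let-7b 2.12-fold and let-7a 2.10-fold. The level of miR-1949 fell 5.83-fold (log2 -2.54, SE 0.30, adjusted p = 5.98e-07), from 1731 ± 105 to 293 ± 77.6 CPM, and was no longer above background in the DOX lanes.

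Of the 5 measured members of the miR-30 family, which is abundant in heart muscle, 3 fell: miR-30a 5.13-fold (log2 -2.36, SE 0.53, adjusted p = 0.00504), miR-30e 4.87-fold and miR-30d 1.79-fold. Without DOX replicate 3 the falls were 10.3-fold for miR-30a and 15.3-fold for miR-30e, which lay above background in 1 of 3 DOX lanes. The log2 changes of miR-30b-5p and miR-30c were 0.07 (SE 0.29) and 0.01 (SE 0.26). The count adjusted over the list alone was also 3, and as the study chose this family on these samples it is not independent evidence of the direction. Among the 5 myomiRs, miR-133b fell 3.22-fold (log2 -1.69, SE 0.31, adjusted p = 0.000618), also 1 member adjusted over the list alone. The other myomiRs did not pass the test: the log2 change was 0.26 for miR-1 (SE 0.23), -0.70 for miR-133a (SE 0.32), 0.21 for miR-208 (SE 0.29) and -1.29 for miR-499 (SE 0.59). Without DOX replicate 3, miR-499 and miR-133a passed, with log2 values of -2.44 and -1.33 (adjusted p = 5.54e-05 for each). The hypoxia-induced miR-210 fell 2.68-fold (log2 -1.42, SE 0.33), or 4.87-fold without DOX replicate 3, to a level above background in 1 of 3 DOX lanes. The p53-responsive miR-34a and miR-194 gave log2 values of -0.74 (SE 0.33, adjusted p = 0.0791) and 0.01 (SE 0.31). Among miRNAs of other cell types, smooth muscle miR-143 fell 2.53-fold while miR-145, made from the same transcript, gave a log2 value of 0.71 (adjusted p = 0.0586). Fibroblast-associated miR-21 fell 1.82-fold and miR-199a-3p rose 1.61-fold, leukocyte miR-150 rose 3.37-fold with overlapping groups, and endothelial miR-126 gave a log2 value of 0.23 (adjusted p = 0.543). Further rises were 2.61-fold for miR-99b, 2.14-fold for miR-290, 2.12-fold for miR-125a-5p, 2.04-fold for miR-151, 1.99-fold for miR-466d and 1.98-fold for miR-15b, and miR-140 fell 2.29-fold to a level above background in no DOX lane. The authors' own correction put miR-290 at its floor in 10 lanes. Of the 18 higher calls, 2 were of miRNAs in which neither group lay above background in all 3 lanes: miR-361 (named for this reason, after its values were seen) and miR-466d, at 219 ± 6.40 CPM in vehicle and 441 ± 149 CPM under DOX.

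By edgeR, 33 of 109 miRNAs passed an adjusted p of 0.05, 18 higher and 15 lower, and 51 had an unadjusted p under 0.05. In 9 of the 33 at least 1 group did not lie above background in all 3 lanes, and the size of those folds depends in part on background. Groups did not overlap for 30 of the 33, and for 46.8% of all tested miRNAs against the 10% that chance gives. As a list, the miR-29 family was lower (adjusted p = 0.00898), a call lost with an estimated correlation (adjusted p = 0.336 with an estimated correlation); 3 members fell adjusted over the list alone. The let-7 family (5 adjusted over the list alone), miR-30 family and myomiR list gave adjusted p of 0.0816, 0.0920 and 0.211. Negative-control and spike-in probes moved by a median log2 of 0.47 (range -0.10 to 1.00). All in vitro DOX lanes were on a cartridge of their own, so this comparison alone cannot tell treatment from cartridge (30 of the 33 calls had the same sign in vivo, where both groups were on the other cartridge), and the count was 69 without DOX replicate 3, 17 without DOX 1, 21 without DOX 2, 18 without vehicle 1, 21 without vehicle 2 and 83 without the 3 least typical samples (in vitro DOX 3, in vivo DOX 1 and MI 3). It was 1 under positive-control scaling, 12 under housekeeping scaling with 0 higher and 12 lower, 25 without a filter with 0 higher and 25 lower, 18 after background subtraction with 9 higher and 9 lower, 21 for miRNAs above background in all lanes and 11 in a fit of these groups alone.

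**Figure D2:**
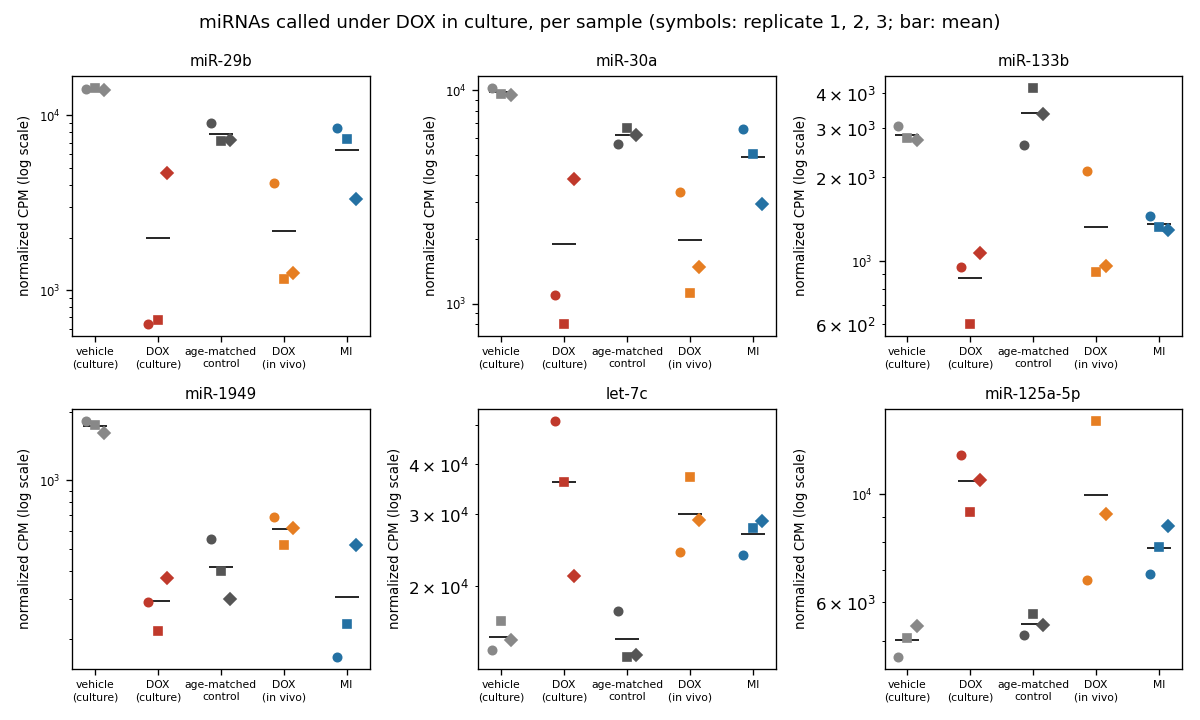
Normalized CPM per sample of miRNAs that changed under DOX, on a log axis, with each group's mean as a bar and symbols for replicates 1 to 3. In vitro DOX replicate 3 and in vivo DOX replicate 1 lie between their controls and the rest of their group for several of these miRNAs.

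The second comparison asked which miRNAs differ in cardiomyocytes of hearts that failed after repeated DOX injections, against age-matched controls. Of the 8 let-7 members, let-7e rose 2.09-fold (log2 1.06, SE 0.28), let-7c 2.05-fold (log2 1.03, SE 0.29), from 14721 ± 2258 to 30147 ± 6575 CPM, and let-7b 2.02-fold (log2 1.01, SE 0.29), each with n = 3 per group. The muscle miRNA miR-133b fell 2.52-fold (log2 -1.33, SE 0.31), from 3379 ± 775 to 1327 ± 669 CPM. The adjusted p was 0.0229 for miR-133b and 0.0451 for the 3 let-7 members. In all 4 the groups did not overlap, which also held for 33.9% of all tested miRNAs.

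No member of the miR-30 family passed the edgeR test. The log2 values were -1.63 for miR-30a (SE 0.52, adjusted p = 0.0847), -1.54 for miR-30e (SE 0.70), -0.72 for miR-30d (SE 0.30), 0.46 for miR-30c and 0.01 for miR-30b-5p. Of these, 1 was lower adjusted over the list alone, which is not independent evidence. Without in vivo DOX replicate 1 the values were -2.25 for miR-30a (adjusted p = 0.0120) and -2.35 for miR-30e (adjusted p = 0.0545). The remaining myomiRs gave log2 values of 0.01 for miR-1, -0.71 for miR-133a, -0.10 for miR-208 and -0.77 for miR-499, which was -1.64 (adjusted p = 0.0439) without DOX replicate 1. Values for miR-210, miR-34a and miR-194 were -0.94 (SE 0.34, adjusted p = 0.0858), -0.47 and -0.17. The next smallest p was that of miR-23a, with a log2 value of 0.96 (SE 0.30, adjusted p = 0.0603). No miR-29 member passed over all miRNAs and 2 were lower adjusted over the list alone, with log2 values of -1.83 for miR-29b (SE 0.74) and -1.49 for miR-29c (SE 0.49). Without DOX replicate 1 these became -2.70 (adjusted p = 0.0360) and -2.17 (adjusted p = 0.00529). Among miRNAs of other cell types the log2 values were 0.54 for miR-126, 0.83 for miR-199a-3p, 0.82 for miR-146a, 1.91 for miR-150 (adjusted p = 0.0847), -1.06 for miR-143 (adjusted p = 0.0747) and 0.53 for miR-145.

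By edgeR 4 miRNAs passed, 3 higher and 1 lower, and 28 had an unadjusted p under 0.05. DESeq2 called 21 and limma on the authors' sum-normalized values 7. The let-7 family was higher as a list (adjusted p = 0.00670; 5 members adjusted over the list alone), but its median turned from 0.71 to -0.03 under housekeeping scaling and the call was lost with an estimated correlation (adjusted p = 0.336 with an estimated correlation). The miR-29, myomiR and miR-30 lists gave adjusted p of 0.0572, 0.114 and 0.257. Control probes moved by a median log2 of -0.47. The count was 21 without in vivo DOX replicate 1, 0 without DOX 2 or DOX 3, 1 without control 1, 0 without control 2 or control 3 and 53 without the 3 least typical samples. Housekeeping scaling gave 0 higher and 29 lower, and other settings gave 1 to 17.

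The third comparison asked which miRNAs differ in cardiomyocytes isolated 4 weeks after MI. The 3 largest rises were in miRNAs linked to fibroblasts and endothelial cells. Fibroblast-associated miR-199a-3p rose 6.04-fold (log2 2.59, SE 0.29, adjusted p = 1.72e-07, n = 3 per group), from 568 ± 60.6 to 3442 ± 711 CPM, and miR-199a-5p 5.20-fold from a level not above background. Endothelial miR-126 rose 4.64-fold (log2 2.21, SE 0.32, adjusted p = 5.55e-06), from 21218 ± 1019 to 98515 ± 45420 CPM, and leukocyte miR-146a rose 3.18-fold (log2 1.67, SE 0.35). All 4 measured members of the miR-15 family, which restrains the cell cycle, rose: miR-322 4.05-fold, miR-195 3.13-fold, miR-15b 1.98-fold and miR-16 1.60-fold, the last also an erythroid miRNA. The muscle miRNA miR-133b fell 2.50-fold (log2 -1.32, SE 0.32, adjusted p = 0.00211), from 3379 ± 775 to 1356 ± 84.3 CPM.

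Not all miRNAs of other cell types passed the test: the log2 values were 1.04 for leukocyte miR-150 (SE 0.61, adjusted p = 0.226), 0.12 for fibroblast miR-10a-5p, 0.19 for fibroblast miR-152, 0.16 for smooth muscle miR-143 (SE 0.34) and -0.08 for miR-145 (SE 0.28). MI replicate 3 stood apart from the other MI samples, with a chi-square per degree of freedom of 17.6 and 15.1 against 2.07 between those, and was lower in several of the miRNAs that rose. Its miR-126 was 46623 CPM against 131043 and 117880, its miR-146a 1827 against 4020 and 5341, its miR-322 2542 against 7969 and 7503, and its miR-195 655 against 1522 and 1635. Without it the log2 changes were 2.55 for miR-126, 2.38 for miR-322 and 1.95 for miR-195. Further rises were 3.42-fold for miR-450a, 2.46-fold for miR-338, 2.19-fold for miR-132, 1.82-fold for let-7c, 1.76-fold for miR-21, 1.69-fold for let-7e and 1.67-fold for miR-25. Lower calls included miR-466d at 3.98-fold, miR-501 at 3.02-fold, miR-3571 at 2.95-fold, miR-3594-3p at 2.83-fold, miR-421 at 2.72-fold, miR-598-5p at 2.65-fold, miR-532-5p at 2.49-fold and miR-544 at 2.25-fold (log2 0.092 under positive-control scaling). The lower calls for miR-466c (log2 -1.27) and the myomiR miR-208 (log2 -1.01) rest on probes that the authors' correction put at its floor in all 15 lanes, and turned to 0.037 and 0.29 under positive-control scaling. Of the 24 lower calls, 9, and of the 17 higher calls, 2 (miR-338 and miR-132) were of miRNAs in which neither group lay above background in all 3 lanes. Control probes moved down by a median log2 of -1.02 (range -1.90 to -0.09). Among the miR-30 family, miR-30d fell 1.90-fold (log2 0.38 under positive-control scaling), the 1 member also called adjusted over the list alone (not independent evidence), and log2 values were -0.35 for miR-30a, -0.54 for miR-30e, -0.35 for miR-30c and -0.27 for miR-30b-5p. The other myomiRs gave log2 values of -0.38 for miR-1, -0.74 for miR-133a (adjusted p = 0.0709) and -0.81 for miR-499. The p53-responsive miR-34a fell 1.98-fold (log2 0.30 under positive-control scaling) at a level not above background in all lanes of either group, and miR-194 and miR-210 gave log2 values of -0.49 and -0.24.

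By edgeR 41 miRNAs passed, 17 higher and 24 lower, and 48 had an unadjusted p under 0.05. Groups did not overlap for all 41, nor for 57.8% of all tested miRNAs. In 22 of the 41 at least 1 group did not lie above background in all 3 lanes. As lists, miRNAs reported raised in rodent heart failure (5 of 9 higher, 5 adjusted over the list alone), fibroblast miRNAs (3 of 5, and 3 adjusted over the list alone) and the miR-15 family (4 of 4, and 4 adjusted over the list alone) were higher, with adjusted p of 0.00634, 0.00670 and 0.0196. The first and the second share miR-21 and both miR-199a arms, and the first and the last share miR-195. These calls were lost with an estimated correlation (adjusted p of 0.242, 0.242 and 0.336 with an estimated correlation). The count was 21 without control 1, 26 without control 2, 25 without control 3, 21 without MI 2 and 68 without the 3 least typical samples, 12 after background subtraction with 10 higher and 2 lower, 43 without a filter with 37 higher and 6 lower, and 10 for miRNAs above background in all lanes. Positive-control scaling gave 53 higher and 1 lower, with 16 calls changed in sign, and housekeeping scaling 5 higher and 32 lower.

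**Figure D3:**
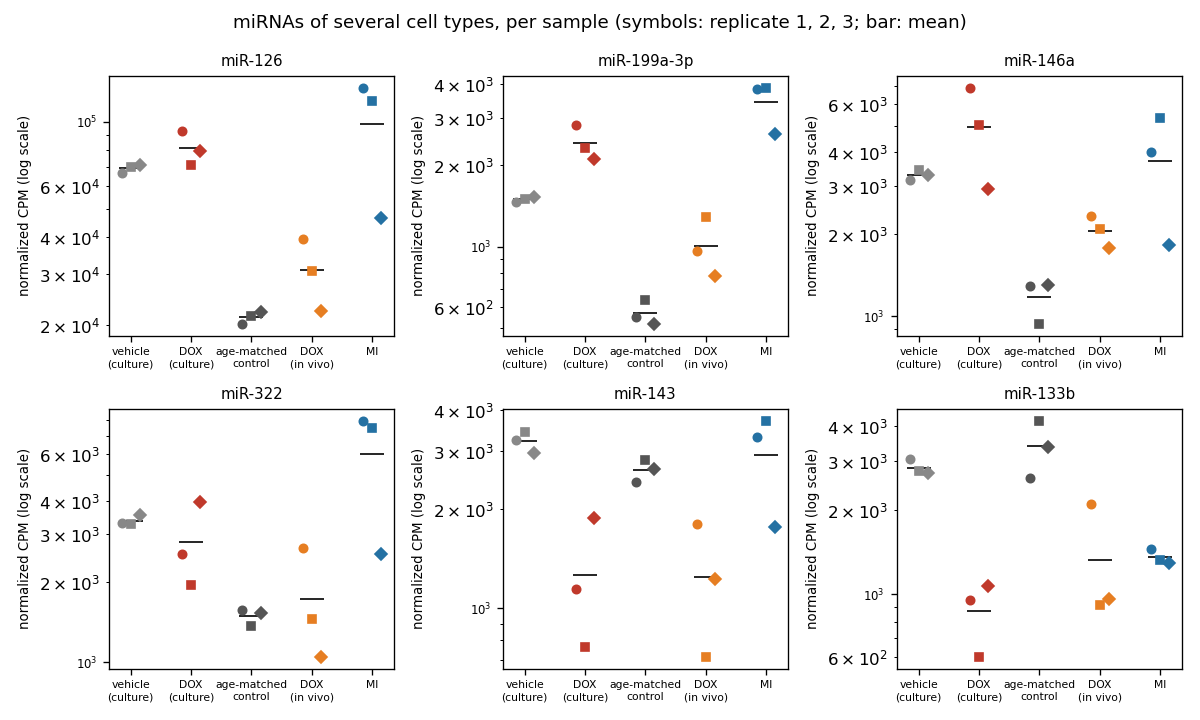
Normalized CPM per sample, on a log axis, of miRNAs of several cell types in the 5 groups, with each group's mean as a bar and symbols for replicates 1 to 3. For miR-126 the mean is 98515 CPM in MI, 69110 CPM in vehicle and 21218 CPM in age-matched controls.

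The fourth comparison set in vivo DOX against MI, that is, both kinds of heart failure without the age-matched controls. In DOX hearts miR-199a-5p was 5.96-fold lower than in MI (log2 -2.58, SE 0.32, adjusted p = 1.16e-06), miR-199a-3p 3.40-fold lower (log2 -1.77, SE 0.27), endothelial miR-126 3.20-fold lower (log2 -1.68, SE 0.31) and miR-21, a miRNA linked to fibrosis, 2.90-fold lower (log2 -1.54, SE 0.32), with n = 3 per group. The let-7 members let-7d and let-7a were 1.71-fold and 1.64-fold higher in DOX and let-7i was 2.13-fold lower. Of the miR-30 family, miR-30c was 1.74-fold higher (log2 0.80, SE 0.27), also the 1 member called adjusted over the list alone (not independent evidence). Under positive-control scaling the higher calls of let-7d, let-7a and miR-30c turned to log2 -0.13, -0.16 and -0.035.

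Other miRNAs lower in DOX hearts were miR-322 at 3.45-fold with overlapping groups, miR-301a at 2.52-fold, miR-143 at 2.33-fold with overlapping groups, miR-338 at 2.32-fold, miR-195 at 2.24-fold, miR-19b at 2.23-fold, miR-27a at 2.01-fold and miR-106b at 1.95-fold. Those higher in DOX hearts were miR-466d at 3.22-fold, miR-501 at 3.05-fold, miR-3589 at 2.94-fold, miR-3571 at 2.87-fold, miR-544 at 2.81-fold, miR-598-5p at 2.73-fold, miR-3594-3p at 2.68-fold, miR-532-5p at 2.42-fold, miR-32 at 2.15-fold, and miR-466c and miR-208 at 2.32-fold and 1.88-fold on probes at the authors' floor. The values of miR-466c and miR-208 turned negative with limma on the sum-normalized values and with the authors' corrected counts. That of miR-208 also did so under positive-control scaling. Of the 20 higher calls, 6, and of the 15 lower calls, 2 (miR-140 and miR-338) were of miRNAs in which neither group lay above background in all 3 lanes, and control probes moved up by a median log2 of 0.62. The myomiRs miR-1, miR-133a, miR-133b and miR-499 gave log2 values of 0.39, 0.03, -0.01 and 0.04, the last -0.83 without DOX replicate 1. Values were -1.28 for miR-30a, -0.99 for miR-30e, 0.20 for miR-30d, 0.28 for miR-30b-5p, 0.52 for miR-34a, 0.32 for miR-194, -0.70 for miR-210 and -0.85 for miR-146a (adjusted p = 0.0552). Without DOX replicate 1, miR-30a and miR-30e gave -1.90 (adjusted p = 0.0118) and -1.81 (adjusted p = 0.0857).

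By edgeR 35 miRNAs passed, 20 higher and 15 lower in DOX, and 50 had an unadjusted p under 0.05. In 21 of the 35 at least 1 group did not lie above background in all 3 lanes. The heart failure list (5 of 9 lower, 5 adjusted over the list alone) and the fibroblast list (3 of 5 lower, 4 adjusted over the list alone) were lower in DOX hearts, with adjusted p of 0.00670 and 0.00634, both lost with an estimated correlation (adjusted p = 0.242 with an estimated correlation for each). The miR-15 family, with 2 members lower, gave an adjusted p of 0.0920. The count was 53 without DOX 1, 21 without DOX 2, 21 without DOX 3, 22 without MI 1, 17 without MI 2 and 72 without the 3 least typical samples. It was 22 under positive-control scaling with 0 higher and 22 lower and 8 calls changed in sign, 19 under housekeeping scaling with 8 higher and 11 lower, 6 after background subtraction with 1 higher and 5 lower, 32 without a filter with 10 higher and 22 lower, and 13 for miRNAs above background in all lanes.

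The fifth comparison set the groups without DOX or MI against each other, vehicle cells in culture and cells isolated from age-matched control hearts. Vehicle cells had 6 h of saline in culture, which the labels do not give for the control cells. Time in culture thus cannot be told apart from other differences between these groups. In vehicle miR-1949 was 4.26-fold higher (log2 2.09, SE 0.31, adjusted p = 3.44e-05, n = 3 per group), 1731 ± 105 against 416 ± 126 CPM. Of the miRNAs of other cell types, miR-126 was 3.26-fold higher (adjusted p = 0.000447), 69110 ± 2129 against 21218 ± 1019 CPM, miR-146a 2.81-fold, miR-199a-3p 2.63-fold and miR-199a-5p 2.27-fold higher. Of the let-7 family, let-7f was lower by edgeR (log2 -0.93, SE 0.27), 7827 ± 891 against 14918 ± 3688 CPM.

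Also higher in vehicle were miR-450a at 2.31-fold, miR-322 at 2.28-fold, miR-338 at 2.27-fold and miR-140 at 2.14-fold, and lower were miR-466d at 2.57-fold, miR-421 at 2.40-fold, miR-3594-3p at 2.22-fold, miR-598-5p and miR-501 each at 2.02-fold, miR-3571 (adjusted p = 0.0278), miR-3596c at 1.96-fold, miR-103 at 1.95-fold and miR-628 at 1.81-fold. Of the 11 lower calls, 4, and of the 9 higher calls, 1 (miR-338) were of miRNAs in which neither group lay above background in all 3 lanes, and control probes moved down by a median log2 of -1.06. No myomiR or miR-30 member passed over all miRNAs or adjusted over the list alone. The log2 values were -0.39 for miR-1, -0.30 for miR-133a, -0.26 for miR-133b, -0.49 for miR-208, 0.15 for miR-499, 0.67 for miR-30a, 0.89 for miR-30e, -0.04 for miR-30c, -0.46 for miR-30d and -0.61 for miR-30b-5p. Values for miR-210, miR-34a and miR-194 were 0.14, -0.19 and -0.47.

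By edgeR 20 miRNAs passed, 9 higher and 11 lower, and 33 had an unadjusted p under 0.05. In 12 of the 20 at least 1 group did not lie above background in all 3 lanes. No list passed with camera in limma, where the fibroblast list had an adjusted p of 0.0540 and the heart failure list 0.0723. The count was 11 without vehicle 1, 5 without vehicle 2, 12 without vehicle 3, 4 without control 1, 10 without control 3 and 54 without the 3 least typical samples. It was 7 after background subtraction with 6 higher and 1 lower, 26 without a filter with 24 higher and 2 lower, 5 for miRNAs above background in all lanes, 67 in a fit of these groups alone, 10 with DESeq2 factors (9 higher and 1 lower) and 13 after quantile normalization. Positive-control scaling gave 16 higher and 0 lower, and housekeeping scaling 3 higher and 25 lower.

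The last comparison asked whether the DOX effect differed between animals and culture. It did for miR-1949: the effect in vivo minus that in vitro was 3.13 on the log2 scale (SE 0.44, adjusted p = 1.37e-05, n = 3 per group). In culture DOX lowered miR-1949, whereas in vivo the log2 value was 0.59 (SE 0.32, adjusted p = 0.241), and vehicle was the only group with miR-1949 above background in all 3 lanes. By edgeR 1 miRNA passed and 10 had an unadjusted p under 0.05, and no list passed with camera. The count was 11 without in vitro DOX 3, with miR-29b, miR-29c, miR-30a, miR-30e, miR-210 and miR-499 then among the calls, 2 without in vivo DOX 3 and 18 without the 3 least typical samples, 2 without a filter and 0 for miRNAs above background in all lanes, a set that leaves out miR-1949. The cartridge is confounded with in vitro DOX here as well.

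Across the 109 miRNAs, which are not independent replicates, the log2 changes under DOX in culture and in vivo had a Pearson r of 0.771 (95% interval 0.682 to 0.838, taking miRNAs as independent) and a Spearman rho of 0.739. Of the 33 miRNAs called in culture, 30 had the same sign in vivo. The miRNAs let-7b, let-7c and let-7e were called higher in both and miR-133b lower in both, where independent calls would give 0.495 and 0.138 shared. These effects have no sample in common. The value was 0.680 under positive-control scaling, 0.0122 after background subtraction, 0.296 without a filter, 0.910 for miRNAs above background in all lanes and 0.869 without the 3 least typical samples.

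**Figure D4:**
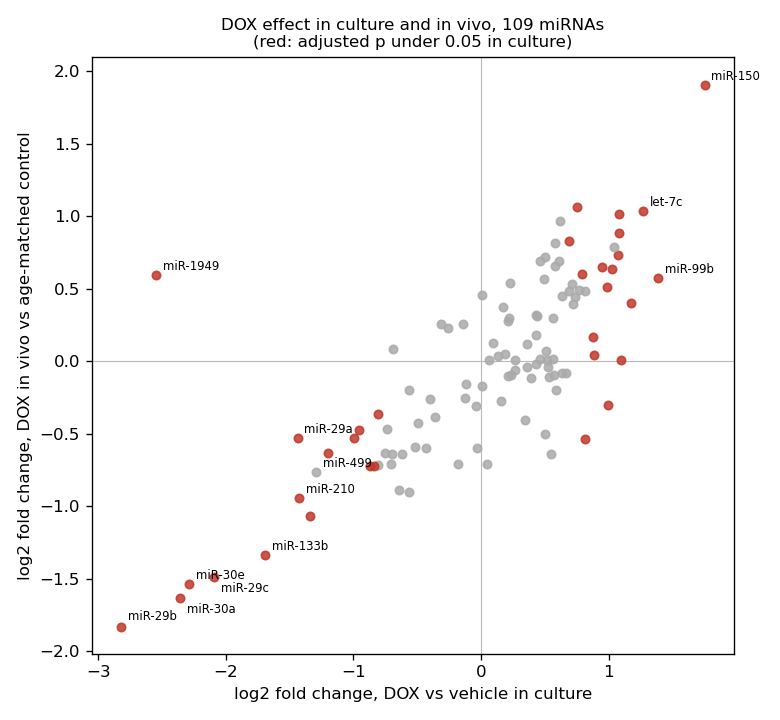
Log2 fold change under DOX in culture (horizontal axis) against that in vivo (vertical axis) for the 109 tested miRNAs, 1 point each, red where the adjusted p in culture was under 0.05. The Pearson r across miRNAs is 0.771, and miR-1949 lies apart with -2.54 in culture and 0.59 in vivo.

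The effects of in vivo DOX and MI share their controls, which alone produces a correlation. The Pearson r across miRNAs was 0.383 (rho 0.414), against a mean of 0.269 in 100 simulations with no shared effect (95% of them 0.046 to 0.465). The covariance was 0.218 against a simulated mean of 0.025 (95% of them 0.004 to 0.048), and 68.8% of signs matched against 58.8%. Both effects raised let-7c and let-7e and lowered miR-133b, where independent calls would give 0.468 and 0.220. In 100 simulations of unchanged groups against these controls, put through the whole edgeR fit, no miRNA was called in both effects (0 higher and 0 lower). The figures for independent calls leave out the shared controls, and the simulations leave out any effect. With separate controls, 1 for one effect and the other 2 for the other, the 6 possible splits gave an r of 0.275 to 0.361, a covariance of 0.171 to 0.210 and 61.5% to 66.1% matching signs. These splits and the simulations through the whole fit were added after the data had been seen, and the lone control is assumed to vary like the other groups.

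Among the housekeeping mRNA probes, Actb measured 925 ± 5.49 CPM of miRNA counts in age-matched controls, 1939 ± 614 in in vivo DOX, 2770 ± 366 in MI, 2061 ± 308 in vehicle and 2575 ± 651 in in vitro DOX (SD, n = 3 each). B2m measured 4703 ± 743 in age-matched controls, 8167 ± 1792 in in vivo DOX, 10525 ± 3345 in MI, 8332 ± 1246 in vehicle and 9771 ± 4385 in in vitro DOX. Rpl19 measured 5662 ± 777 in in vivo DOX, 3076 ± 574 in age-matched controls, 3006 ± 1037 in MI, 2789 ± 550 in vehicle and 3668 ± 172 in in vitro DOX. Gapdh means lay between 27576 ± 3477 in age-matched controls and 31719 ± 12043 in in vivo DOX, with 30524 ± 6903 in in vitro DOX, 28780 ± 5338 in vehicle and 28728 ± 10878 in MI.

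The authors' quantile tables list an unadjusted p under 0.05 for 61 of 420 miRNAs under in vitro DOX, 41 of 420 under in vivo DOX and 47 of the miRNAs listed after MI. Adjusted by the Benjamini-Hochberg method these become 1, 0 and 3 miRNAs. The authors' log2 ratios and those of the edgeR model had a Pearson r across miRNAs of 0.879, 0.921 and 0.883. Of the edgeR calls listed there, 24 of 33, 2 of 4 and 26 of 39 had an authors' p under 0.05 in the same direction, and 3 had the opposite direction, all after MI: miR-208, miR-466c and miR-25.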

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

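The tests of exchanged labels, of the share of other cell types, of scaling, of low age-matched controls, and of cartridge and background for the alike DOX effects were chosen after the results had been seen, and the other tests before. Several values stood out from the rest of the data. For miR-1949 the DOX effect differed between animals and culture by 3.13 on the log2 scale, by the test of the difference itself. Its mean was 1731 CPM in vehicle but 416 CPM in age-matched controls, above background in 1 of 3 lanes. A fall in vivo could therefore hardly be seen, and the cartridge is confounded with in vitro DOX. Housekeeping mRNA probes, which the miRNA comparisons do not use, had all 3 treated samples above all 3 controls in 6 of 12 probe and comparison pairs, and the smallest p of an exact 3 against 3 test is 0.1. The fold of means was 1.31 for Rpl19 under in vitro DOX. It was 2.10 for Actb, 1.74 for B2m and 1.84 for Rpl19 under in vivo DOX. It was 2.99 for Actb and 2.24 for B2m after MI. MI replicate 3 differed from the other MI samples by a chi-square per degree of freedom of 17.6 and 15.1, against 2.07 between those.

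Other ways of parting the 6 samples of a comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave the most calls, so 1 of 10 splits reached its count, in in vitro DOX (33 calls, highest other 0), in vivo DOX (4, highest other 0), MI (41, highest other 0), in vivo DOX against MI (35, highest other 4) and vehicle against age-matched controls (20, highest other 0). For list calls, 1 split reached the real count under in vitro DOX (1 list, highest other 0), 3 under in vivo DOX (1, highest other 1), 2 after MI (3, highest other 3) and 2 for in vivo DOX against MI (2, highest other 2). For the difference of the DOX effects, 12 of 100 splits gave at least the 1 call, so chance is not excluded for that count. The highest gave 48 calls, many times the real count, which points to a structure of the samples. That split kept the in vitro groups whole and placed in vivo DOX replicate 1 with 2 controls, and whether this placement produced the calls was not tested.

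After MI, endothelial miR-126, 3 of 5 measured fibroblast miRNAs (miR-199a-3p, miR-199a-5p and miR-21) and 1 of 2 measured leukocyte miRNAs (miR-146a) were higher than in age-matched controls. The panel held 8 fibroblast and 6 leukocyte miRNAs. Those not measured were not above background in the 3 lanes needed. An equal rise of every other cell type, as a lower share of cardiomyocytes might give, was tested with 1 miRNA for each of 2 cell types. Endothelial miR-126 rose by 2.06 (log2) more than smooth muscle miR-143, so these 2 did not rise alike. This cannot exclude a lower share of cardiomyocytes, since the cells that hold miR-143 in these samples were not determined. The rises of miR-126, miR-199a-3p, miR-199a-5p and miR-146a exceeded 2 SE under 6 scalings and after background subtraction. One of these scalings was TMM, by which the members were chosen. The rise of miR-21 did so in 6 of 7 settings. The 4 were parted from miR-21 after the values were seen. The result shows only that these 4 rises did not depend on the settings tried, and scaling and background stay open for miR-21. Low controls as the whole cause cannot be excluded. Of the 5 members, 4 were also lower in in vivo DOX than in MI, a comparison without those controls. In vivo DOX may itself be low, and vehicle, the other group without DOX or MI, lay above the controls too. Vehicle cells also had 6 h in culture, so they are not a second reference of the same kind. Mean CPM in vehicle against MI were 69110 and 98515 for miR-126, and 3307 and 3729 for miR-146a. They were 1498 and 3442 for miR-199a-3p, 729 and 1657 for miR-199a-5p, and 4531 and 6307 for miR-21. Vehicle was not tested against MI. More endothelial cells and fibroblasts may account for the rise, although the labels call the cells pure cardiomyocytes (miR-126 reached 98515 CPM), and so may a change within the cardiomyocytes, and neither was tested.

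DOX shifted miRNAs alike in culture and in animals. The cartridge as the whole cause is excluded, since both in vivo groups were on the other cartridge and r across miRNAs was 0.771. Lane background is excluded for the 33 miRNAs averaging over 10 times the background, where r was 0.936, whereas r over all tested miRNAs was 0.0122 after background subtraction. The same RNA in lanes of both groups is excluded, since the lowest chi-square per degree of freedom between their lanes was 42.0. A shared response of cardiomyocytes to DOX may explain the likeness, as a hypothesis found and tested on the same data. Whether RNA quality or the assay in the DOX samples contributes was not tested. Mean miR-145 was 73539 CPM under DOX against 44881 in culture, and 77582 against 53646 in vivo. Mean miR-143, made from the same transcript, went the other way, with 1263 against 3210 and 1248 against 2630.

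In vitro DOX replicate 3 and in vivo DOX replicate 1 stood apart from their groups, with correlations of 0.963 to 0.968 and 0.972 to 0.974 with controls against 0.903 to 0.917 and 0.948 to 0.951 with their own group. An exchange of labels with a control is excluded in both, since 0 controls were out of place, while a single wrong label stays open. In vitro DOX 3 correlated best with MI replicate 3, at 0.976, while MI 3 correlated at 0.966 and 0.970 with its own group. An exchange or mixture with MI 3, or a fault common to these lanes, was not tested and stays open. Lane background is excluded for in vitro DOX 3, with a median difference of 0.955 (log2) over bright miRNAs against 0.342 between the other samples, and stays open for in vivo DOX 1, at 0.649 against 0.357. A smaller response of the same kind may explain in vitro DOX 3, whose changes had a slope of 0.287 (SE 0.0397, r 0.573) on those of the other samples. For in vivo DOX 1 the slope was 0.317 (SE 0.0536) with r 0.497, which left this open. Each slope takes both sets of changes from the same controls, which alone can make it positive. For in vitro DOX 3 the cartridge that all in vitro DOX lanes share could do so too.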

How the results depend on the processing

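Quantile normalization, the stricter filter, the omission of 3 samples and all alternatives for the agreement of the DOX effects were chosen after the data had been seen, the others before. Where no reason is given, the cause was not tested. Of the log2 changes of named miRNAs over all alternatives, 2911 stayed on their side of the threshold, 506 lost it, 95 gained it and 14 reversed. Of list results 1654 stayed, 59 gained and 15 lost it. Reversal was counted only where the main fit or the alternative gave a call. Results called in neither count as stayed, whatever their sign. Calls held in every omission of 1 sample, every scaling and after background subtraction numbered 1 of 33 for in vitro DOX, 0 of 4 for in vivo DOX, 5 of 41 for MI, 5 of 35 for in vivo DOX against MI, 3 of 20 for vehicle and 1 of 1 for the difference of DOX effects. The r shared by in vivo DOX and MI stayed within its interval, also with separate controls, a test added after the data had been seen. In the order of the 5 group comparisons, the median of all miRNAs moved from its value under TMM by -0.35, 0.32, 1.29, -0.81 and 0.78 under positive-control scaling, by -0.32, -0.74, -0.59, -0.10 and -0.38 under housekeeping scaling, and by -0.19, 0.10, 0.11, 0.00 and 0.22 with DESeq2 factors. The authors' quantile values are given only as group means, so limma was not run on them.

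Counts are of called miRNAs. With DESeq2 factors in vivo DOX gave 7 and vehicle 10 (9 higher, 1 lower), and the split was 9 higher and 22 lower for in vitro DOX, 6 and 1 for in vivo DOX and 22 and 19 for MI. With library size alone it was 12 and 15 for in vitro DOX, 19 and 17 for MI, 15 and 21 for in vivo DOX against MI and 9 and 5 for vehicle. Positive-control scaling gave 1 for in vitro DOX (0 higher) and 22 for in vivo DOX against MI (0 higher), and splits of 5 and 0 for in vivo DOX, 53 and 1 for MI and 16 and 0 for vehicle. Housekeeping scaling gave 12 for in vitro DOX (0 higher), 29 for in vivo DOX (0 higher) and 19 for in vivo DOX against MI (8 higher), and splits of 5 and 32 for MI and 3 and 25 for vehicle. DESeq2's own test gave 21 for in vivo DOX, limma on the sum-normalized values 7, the fit without robust estimation 8 and the replicate term 1. Equal replicate numbers were not shown to pair samples. After background subtraction counts were 18, 2, 12, 6 and 7, with 9, 2, 10, 1 and 6 higher. Without a filter, over all 420 probes, they were 25, 5, 43, 32 and 26, with 0, 5, 37, 10 and 24 higher. With the filter on all 15 lanes they were 21, 17, 10, 13 and 5, from fewer miRNAs tested, and 0 for the difference of DOX effects, against 2 without a filter. Fits of the compared groups alone gave 11 for in vitro DOX, 13 for in vivo DOX and 67 for vehicle. Quantile normalization gave 7 for in vivo DOX and 13 for vehicle, and the stricter filter 9 for in vivo DOX. Without the 3 least typical samples counts were 83, 53, 68, 72 and 54, and 18 for the difference. Omission of 1 sample, where the remaining pair is taken to vary like the other groups, gave 17 to 69 for in vitro DOX, 0 to 21 for in vivo DOX, 21 to 34 for MI, 17 to 53 for in vivo DOX against MI, 4 to 18 for vehicle and 1 to 11 for the difference.

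The number of list calls, 7, became 13 with limma on the sum-normalized values, 20 without a filter, 2 with the filter on all lanes, 12 without the 3 samples, 0 with an estimated correlation and 7 to 12 on omission of 1 sample. The r for the agreement of the 2 DOX effects became 0.680 under positive-control scaling, 0.0122 after background subtraction, 0.296 without a filter, 0.910 with the filter on all lanes, 0.869 without the 3 samples and 0.673 to 0.834 on omission of 1 sample.

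Reversed log2 values under positive-control scaling, which moves the median as given above, were 0.037 for miR-466c, 0.092 for miR-544, 0.38 for miR-30d, 0.29 for miR-208 and 0.30 for miR-34a after MI, and -0.035 for miR-30c, -0.15 for miR-208, -0.13 for let-7d and -0.16 for let-7a in in vivo DOX against MI. In the same comparison miR-466c and miR-208 each became -0.38 with limma on the sum-normalized values and -0.47 with the authors' corrected counts, both of which put these probes at a floor. The value of miR-499 became -0.88 without the 3 samples. Of the 109 tested miRNAs, 58 lay above the lane background (11.8 to 47.2 counts) in all 15 lanes, and the values of the others rest in part on lanes at or under background.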

Other observations

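What is described here was chosen after the data had been seen, from lists fixed before. MI and vehicle each share the age-matched controls as reference, and 7 miRNAs were called higher and 9 lower in both, with an r across miRNAs of 0.735. In 100 simulations of unchanged groups against the same controls the mean r was 0.255 (95% of them 0.084 to 0.408) and no miRNA was called in both (0 higher and 0 lower). The covariance was 0.436 against a simulated mean of 0.022, and with separate controls r was 0.622 to 0.685 and the covariance 0.406 to 0.425 over the 6 splits. Control probes were also lower than in the age-matched controls, by a median log2 of -1.02 in MI and -1.06 in vehicle. Neither the simulations nor the separate controls can remove a background difference that all control lanes share. After background subtraction MI kept 10 higher and 2 lower calls, and vehicle 6 higher and 1 lower. The miR-17-92 clusters, linked to cell proliferation, had 6 measured members: miR-25 rose after MI, and miR-19b and miR-106b were lower in in vivo DOX than in MI. As a list they did not pass in any comparison (lowest adjusted p 0.410), nor did the miR-23/24/27 cluster (lowest adjusted p 0.758), of which miR-27a alone was called, in in vivo DOX against MI. The miR-15 family did not pass under DOX, with adjusted p of 0.758 in culture and 0.527 in vivo.

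Of the 44 Dlk1-Dio3 miRNAs on the panel 1 was measured, miR-543, with log2 values from -0.18 to 0.43 and no call by edgeR in any of the 6 comparisons. None of the 5 miR-200 members and none of the 8 brain, liver and islet miRNAs on the panel was above background in the 3 lanes needed. The erythroid list had 1 measured member, miR-16, which rose after MI and gave log2 values of 0.10 and 0.13 under DOX in culture and in vivo.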
